A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

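Ribosome-bound RNA was depleted of ribosomal RNA and made into libraries with a stranded total RNA kit, per the labels' protocols, after treatment with 100 µg/ml cycloheximide, 2 h on IgG beads and, for unbound ribosomes, a 10% to 50% sucrose gradient. The authors deposited a file of raw counts per feature for each of 7 libraries. Reads were aligned with TopHat2 2.0.9 to sacCer3, and DESeq and DESeq2 were used, per the submitters' processing notes; the counting program and its strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. The authors' deposited result tables hold log2 fold changes and adjusted p-values from DESeq2, per the file headers and the processing notes. A deposited sheet named as normalized holds values equal to the raw counts of the count files in all 5896 rows whose names matched, in each of the 4 columns mapped to a library. The authors' 2 other normalized sheets hold counts divided by a factor per library (a signal in the deposited values) and were compared column with column but not tested.

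Each count file holds 6341 features and 5 closing lines for reads given to no feature. These closing lines stayed out of library sizes and tests. Reads in no feature were 3.37% to 7.48% and ambiguous reads 0.15% to 2.75% of the reads counted, ambiguous or in no feature. The line for alignments that were not unique held 11530659 to 18980582 in 5 libraries and 0 in replicate 3 of both groups, so such reads were handled or listed differently in replicate 3. Names were matched to the RefSeq table of assembly R64, the assembly of sacCer3, from which coordinates are given: 6052 features matched by symbol or locus tag, 46 by synonym and 243 not, 226 of the latter named like tRNAs. Coding length is the annotated span of the gene, introns included, and 96.3% of the spans of 5873 nuclear protein-coding genes were multiples of 3, so they hold no UTRs. The intron-bearing genes, many of them ribosomal protein genes, have spans longer than their coding sequence.

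The main test was edgeR 4.0.16 (R 4.3.3) with trimmed-mean scaling, its default filter on low counts, a quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change divided by the square root of the F value. Minus_Rps26 and Plus_Rps26 were fitted alone, and both comparisons with Rps3_TAP were fitted over all 7 libraries, where the single library shares the spread of the others. The series describes biological replicates. Plus_Rps26 replicate 2 carries a flowthrough number 1 in its description and replicate 2 in its title, and the title was used. The replicate number pairs eluate and flowthrough through the purification protocol; deviations of same-numbered libraries from their group means correlated at -0.20, 0.41 and 0.01, and the log2 ratios of replicate 1 correlated with those of replicates 2 and 3 at 0.18 and 0.24, against 0.91 between replicates 2 and 3. Chi-square values of 150.7 to 607.6 per degree of freedom separated all replicate libraries of a group, so none was a repeat of another.

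The 27 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), repeated with an estimated correlation and with fry. The base tests used Fisher's exact test over 48 pairs of position, -12 to -1, and base. The design called for sequence from a reference; it was taken instead from the authors' deposited column of 20 bases before each start codon, which covered 5684 nuclear protein-coding genes. Its last base was taken as -1, since A was most frequent 3 bases from its end, as it is at -3 of yeast start codons. Rank correlations used 100000 permutations in Python 3.11.15 with numpy 2.4.6, and Fisher's tests scipy 1.17.1. The covariance of comparisons that share controls was set against 20 draws of unchanged groups. On simulated counts with 200 changed genes the test recovered 92.3% of 4-fold and 21% of 2-fold changes between Minus_Rps26 and Plus_Rps26 over 5668 features, 46.7% and 2.3% between Minus_Rps26 and Rps3_TAP and 43% and 3% between Plus_Rps26 and Rps3_TAP over 5815 features.

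Genes are named by a rule fixed, like the lists, the designs and most alternatives, before the data were examined: the engineered genes first; the 10 highest and 10 lowest log2 fold changes between Minus_Rps26 and Plus_Rps26 among called protein-coding genes with a mean of 10 CPM or more and no overlap between groups, leaving out engineered genes and auxotrophic markers; up to 2 rises and 2 falls per list, or its 2 most abundant members where fewer than 2 were called; every called gene of the Hog1 and Rim101 lists; and the 5 highest and 5 lowest in each comparison with Rps3_TAP. Alternatives were other scaling, DESeq2 1.42.0, limma-voom, no filter, nuclear protein-coding genes alone, a replicate block, other sets of libraries, each library left out, a fold of 2 as well, and for the sequence tests other gene sets, covariates and scores. The leaving out of whole replicate pairs, the removal of the coding length trend by a loess offset (span 0.5) and the repeated use of replicate 1 were added after the data had been seen.

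In the authors' deposited results 1610 genes passed an adjusted p of 0.05 between Minus_Rps26 and Plus_Rps26 (742 higher and 868 lower), of which 876 were among the 907 called here and 1486 among the 1552 called here by DESeq2. Between Minus_Rps26 and Rps3_TAP 2668 genes passed in the authors' deposited table, and between Plus_Rps26 and Rps3_TAP 208. The normalized counts deposited for the first of these held replicate 1 in the column named for replicate 3, as described below.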

Results

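Sequencing counted the mRNA bound to ribosomes that lacked or contained Rps26, a small-subunit ribosomal protein that sits at the mRNA exit channel. The budding yeast strain carried RPS3 and RPS26A under the galactose-induced, glucose-repressed GAL1 promoter, a deletion of RPS26B, and a plasmid-borne TAP-tagged Rps3 that doxycycline keeps off. Cells grown in galactose with 0.2 µg/ml doxycycline were moved to glucose medium without it for 4 h, so that ribosomes made after the shift carry the tag. Tagged ribosomes were taken up on IgG beads and make up the group Minus_Rps26 (3 libraries), and untagged ribosomes recovered from a sucrose gradient of what the beads left behind make up Plus_Rps26 (3 libraries). Rps3_TAP is a single library of bead-purified ribosomes from another strain, with a TAP tag on RPS3 and grown to mid-log phase in glucose medium. Counts over annotated features came to 11590456, 17136240 and 21405499 in replicates 1, 2 and 3 of Minus_Rps26, 9605899, 12387735 and 15279242 in those of Plus_Rps26 and 16145589 in Rps3_TAP.

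RPS26A (YGL189C, sacCer3 chromosome VII, 148229 to 148588) stood at 34.9 ± 9.37 CPM (counts scaled to library size times edgeR's trimmed-mean factor over 7 libraries; SD, n = 3) in Minus_Rps26 and 85.3 ± 32.9 CPM (SD, n = 3) in Plus_Rps26, against 10100 CPM in Rps3_TAP, which is 169 times the mean of the other 6 libraries. RPS26B (YER131W, chromosome V, 423952 to 424311) had 13, 15 and 17 counts in Minus_Rps26 and 10, 142 and 11 counts in Plus_Rps26, against 14293 counts in Rps3_TAP. The 142 counts lie in Plus_Rps26 replicate 2, which had 1042 counts of RPS26A against 545 to 1075 in the other 5 libraries of the strain, so reads shared between these near-identical copies do not account for them, and their source was not tested. RPS3 (YNL178W, chromosome XIV, 302680 to 303402), which the plasmid supplies, ranged from 1450 to 3560 CPM in Minus_Rps26 and stood at 348, 6300 and 8330 CPM in Plus_Rps26, with 7820 CPM in Rps3_TAP. URA3, the marker of the pCM189 plasmid, had 25.3 to 104 CPM in the 6 libraries of the depletion strain and 1 count in Rps3_TAP. Between the classes RPS26A was lower in Minus_Rps26 by a log2 fold change of -1.30 ± 0.35 (SE; edgeR adjusted p = 0.0392), while RPS26B (-3.13 ± 0.99; adjusted p = 0.0518) and RPS3 (-1.09 ± 0.81; adjusted p = 0.351) did not pass. The RPS26A call did not hold with the replicate block (adjusted p = 0.124), with total-count scaling (-0.43) or with the coding length trend removed (-0.54), and its log2 ratio in replicate 1 was -0.12. RPS26B stood at -0.65 without Plus_Rps26 replicate 2 and at -2.02 with the replicate block. RPS3 stood at -0.05 with total-count scaling and -0.35 with the block, and its log2 ratios were 2.07, -0.83 and -2.01 in replicates 1, 2 and 3. These values concern mRNA and do not measure Rps26 protein in the ribosomes.

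**Figure D1:**
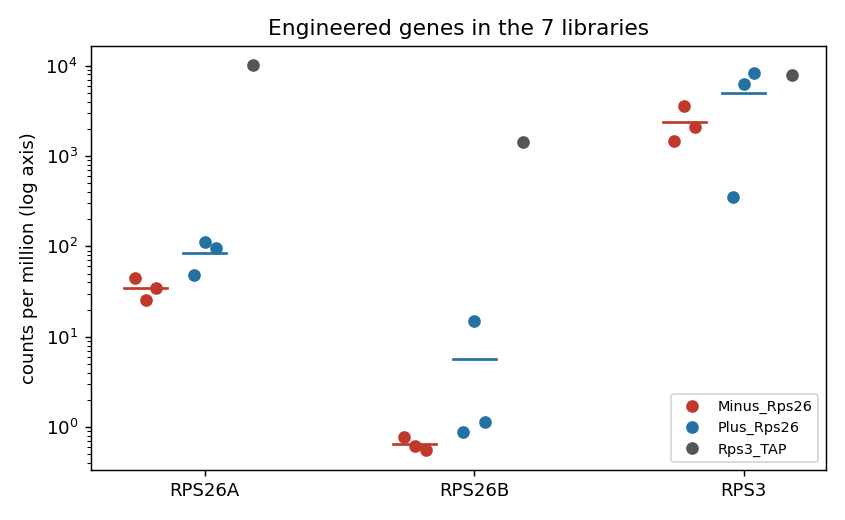
CPM (log axis, trimmed-mean scaling over 7 libraries) of RPS26A, RPS26B and RPS3. Each point is a library and each horizontal line the mean of 3; RPS26A stayed at or under 111 CPM in the 6 libraries of the depletion strain against 10100 CPM in Rps3_TAP, and Plus_Rps26 replicate 1 had 348 CPM of RPS3.

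The comparison of Minus_Rps26 with Plus_Rps26 asks which mRNAs associate differently with the 2 classes of ribosomes. Messages of 91 of 135 cytosolic ribosomal protein genes, 6 of 10 histone genes and 5 of 20 genes of glycolysis and fermentation fell in Minus_Rps26, and 6 of 26 of the Hog1 pathway rose, as did MLP1 and MLP2 of the nuclear pore and the repair gene RAD50. No list passed with an estimated correlation (adjusted p = 0.713 for each of these). Of 5668 features tested, 907 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 459 of them higher and 448 lower in Minus_Rps26; DESeq2 called 1552. With libraries scaled by total counts alone the median of all genes moved from 0.03 to 0.75, and 1042 genes were called higher and 37 lower; each of the 82 genes named by rule had a higher log2 fold change with it. From here CPM between these 2 groups are scaled over their 6 libraries. The genes that rose were long, with a median coding length of 3238.5 bases over 458 nuclear genes, and those that fell were short, with a median of 610.5 bases over 418 genes, against 1242 bases over all 5534 tested. Taking the replicate number as a block, since eluate and flowthrough come from 1 lysate, edgeR called 0 genes (1990 at an unadjusted p under 0.05). The smallest adjusted p of the unblocked test was 0.0357, so every call lay between 0.0357 and the threshold. In edgeR 0 genes were called without Minus_Rps26 replicate 2 (1620 at an unadjusted p under 0.05) or 3 (1200) or Plus_Rps26 replicate 2 (1357) or 3 (1598), 214 without Minus_Rps26 replicate 1 and 2495 without Plus_Rps26 replicate 1.

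Among called protein-coding genes with a mean of 10 CPM or more whose libraries did not overlap between groups, engineered genes aside, those with the 10 largest rises and falls are named next. EAF1 (YDR359C, chromosome IV, 1191936 to 1194884), a subunit of the NuA4 histone acetyltransferase, went from 19.12 ± 8.41 CPM in Plus_Rps26 to 80.84 ± 37.62 CPM in Minus_Rps26 (SD, n = 3 each), a log2 fold change of 2.08 ± 0.42 (SE; edgeR adjusted p = 0.0357). MLP1 and MLP2, which encode filaments of the nuclear pore basket, rose by log2 fold changes of 2.07 ± 0.60 and 1.88 ± 0.42 (SE). ESC1, which encodes a protein of the nuclear periphery, rose 4.05-fold, and RAD50, a subunit of the Mre11 complex of DNA repair, rose 4.02-fold. SNT1, a subunit of the Set3 histone deacetylase complex, rose 4.02-fold and SPP41 4.04-fold. ULS1, a Swi2/Snf2-type protein, rose 3.95-fold, SPO14, a phospholipase D, 3.72-fold and SWH1, an oxysterol-binding protein, 3.67-fold. All of these 10 genes had coding lengths of 2949 bases or more, and with the replicate block none of them was called (adjusted p = 0.117 for each). With the coding length trend removed none was called either, and their log2 fold changes ran from 0.55 for SPO14 to 1.16 for EAF1, with MLP1 at 0.73. Without Plus_Rps26 replicate 1 MLP1 stood at 3.30 and SPP41 at 2.79. Each of the 10 rises was smaller in replicate 1 (log2 ratios from 0.54 for SPP41 to 1.11 for RAD50) than in replicates 2 and 3.

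The falls among these genes were led by RPL41B (YDL133C-A, chromosome IV, 221724 to 221801), whose product is the smallest ribosomal protein. It stood at 203.3 ± 66.2 CPM in Minus_Rps26 and 2044 ± 1433 CPM in Plus_Rps26 (SD, n = 3 each), 10.1-fold lower with a log2 fold change of -3.33 ± 0.65 (SE; edgeR adjusted p = 0.0357). RPL41A was 5.10-fold lower, RPS28B 7.77-fold, RPS12 6.08-fold and RPS25A 5.13-fold. ASC1, the ribosome-bound homologue of RACK1, was 5.82-fold lower, and PGK1, the glycolytic phosphoglycerate kinase, 5.14-fold lower. VMA16, a subunit of the vacuolar proton pump, was 5.88-fold lower, YJR112W-A 6.29-fold and DAL3, an enzyme of allantoin degradation, 5.59-fold. RPL41A and RPL41B are near-identical copies, so the split of reads between them is uncertain. All 10 had a log2 ratio nearer 0 in replicate 1, from -0.68 to -0.21, than in replicates 2 and 3, and an adjusted p of 0.117 with the replicate block. With total-count scaling RPL41B stood at -2.34 and PGK1 at -1.38, and with the coding length trend removed at -2.19 and -2.36. RPS28B, RPS12, RPS25A, RPL41A and YJR112W-A stood at -2.04, -1.92, -1.58, -1.27 and -1.91 with that trend removed. Without Plus_Rps26 replicate 3 ASC1 stood at -1.90 and PGK1 at -1.70. Outside these genes, small nucleolar RNAs such as snR45 (-4.76) had larger falls.

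Cytosolic ribosomal proteins moved together. Of 54 small subunit genes 34 fell and 0 rose, and of 81 large subunit genes 57 fell and 0 rose; adjusted over the list alone, 52 and 73 fell. The medians were log2 fold changes of -1.23 and -1.33, and all 135 values were negative, with medians of -0.39 and -0.50 when libraries were scaled by total counts alone. Both lists passed camera with a preset correlation (adjusted p = 9.89e-22 and 1.68e-25), but not with an estimated correlation, where the adjusted p was 0.713 for each, as it was for all 11 lists that passed. With the coding length trend removed both passed with the preset correlation, at medians of -0.88 and -0.98 (camera adjusted p = 2.71e-20 and 4.59e-24). Coding lengths here include introns, so the trend may be removed too little for intron-bearing members. Ribosomal protein genes made up 23.7%, 21.9% and 17.8% of protein-coding counts in replicates 1, 2 and 3 of Minus_Rps26, 30.9%, 42.8% and 41.0% in Plus_Rps26 and 36.3% in Rps3_TAP.

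Other lists that passed camera in the same direction were glycolysis and fermentation, histones, the nuclear-encoded respiratory chain, mitochondrial ribosomal proteins, mitochondrially encoded mRNAs and non-coding RNAs. Of 20 glycolysis and fermentation genes 5 fell and 0 rose (8 and 0 adjusted over the list alone; median -0.84), with PGK1 and the triosephosphate isomerase gene TPI1 (3.43-fold lower) at the head; GPM1, ADH1 and TDH2, named after their values were seen, were the others. Of 10 histone genes 6 fell (8 adjusted over the list alone), HHT1 by 3.24-fold and HTA2 by 3.20-fold. Of 37 respiratory chain genes 11 fell (13 adjusted over the list alone), among them the cytochrome c gene CYC1, 3.47-fold lower, and the ATP synthase gene ATP5, 3.22-fold lower. Of 68 mitochondrial ribosomal protein genes 6 fell (5 adjusted over the list alone), including MRP2, 3.73-fold lower, and RSM19, 3.30-fold lower. The share of mitochondrial ribosomal protein genes that fell was near that of all features (448 of 5668). With total-count scaling, where the median of all genes sat at 0.75, the medians of these last 2 lists turned positive, to 0.16 and 0.22, and those of glycolysis and histones were -0.01 and -0.25. With the coding length trend removed neither passed camera, the respiratory chain at a median of -0.00 (adjusted p = 0.458) and mitochondrial ribosomal proteins at -0.02 (adjusted p = 0.891), while histones passed at a median of -0.42 (adjusted p = 0.0493), a call lost with the replicate block as well. With the trend removed HHT1, HTA2, CYC1, MRP2 and RSM19 stood at -1.02, -1.01, -1.08, -1.12 and -0.87, and MRP2 stood at -1.31 without Plus_Rps26 replicate 2. Glycolysis and fermentation passed camera with the trend removed, at a median of -1.06 (adjusted p = 1.13e-09).

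Non-coding RNAs and mitochondrial transcripts split by replicate. Of 33 non-coding RNAs, such as the small nucleolar RNAs snR45 (27.0-fold lower) and snR31 (24.1-fold lower), 21 fell and 0 rose (30 and 0 adjusted over the list alone), although both were higher in Minus_Rps26 in replicate 1, with log2 ratios of 1.15 and 1.20. Without Plus_Rps26 replicate 3 their log2 fold changes were -3.56 and -3.77, and -5.37 and -5.21 without Plus_Rps26 replicate 1. The list's median log2 ratio of Minus_Rps26 over Plus_Rps26 was 0.60 in replicate 1, -2.69 in replicate 2 and -3.76 in replicate 3. Non-coding RNA took 7.0%, 2.4% and 1.7% of counts in replicates 1, 2 and 3 of Minus_Rps26, 7.0%, 17.4% and 26.7% in Plus_Rps26 and 13.4% in Rps3_TAP, with 95% Wilson intervals of at most ± 0.022 percentage points that cover counting error only. None of the 8 mitochondrially encoded mRNAs was called (0 also adjusted over the list alone), although the list passed camera (adjusted p = 0.013; 0.0626 with the replicate block) and did not without Plus_Rps26 replicate 3; the median ratio was 1.61 in replicate 1 and -3.53 and -4.09 in replicates 2 and 3. COX1 stood at 405.8 ± 466.7 CPM in Minus_Rps26 and 1164 ± 714 CPM in Plus_Rps26 (SD, n = 3 each), and COX2 at a log2 fold change of -0.77 ± 0.68 (SE). Without Minus_Rps26 replicate 1 COX1 and COX2 stood at -3.09 and -2.15, against -1.52 for COX1 with all libraries, and COX2 turned to 0.17 with total-count scaling.

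Lists that passed camera toward Minus_Rps26 were the Hog1 signalling pathway, ribosome assembly factors and cell cycle regulators. Of 26 genes of Hog1 signalling, the osmotic stress kinase cascade, 6 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.79, camera adjusted p = 0.000334). These were the mucin-type osmosensors HKR1 (3.36-fold) and MSB2 (2.34-fold), the kinases STE20 (2.43-fold), SSK2 (2.29-fold) and SSK22 (2.15-fold), and CDC24 (2.40-fold), an exchange factor for Cdc42. The median ratio of the list was -0.01 in replicate 1, 0.89 in replicate 2 and 1.19 in replicate 3, and its median coding length was 2061 bases. YPD1, whose product passes phosphate to the regulators of the cascade and which is named after its values were seen, was the fall in the list alone (log2 fold change -0.65). With each library's trend with coding length removed, the list passed camera (adjusted p = 0.039) at a median of 0.19, with HKR1, STE20, CDC24 and MSB2 at 0.36, 0.43, 0.47 and 0.03, and SSK2 and SSK22 turned to -0.08 and -0.04; with the replicate block as well the list no longer passed. Osmotic stress targets of the pathway did not pass (0 of 18 called, also adjusted over the list alone; camera adjusted p = 0.487), with GPP1 at -0.84 ± 0.33 and HSP12 at -1.64 ± 0.97 (SE).

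Of 77 ribosome assembly factors 6 rose and 3 fell, the same counts adjusted over the list alone. Over all 5668 features 459 rose and 448 fell, so rises here and in the cell cycle list below were about as frequent as among all features. SDA1 rose 3.05-fold and the giant ATPase gene MDN1 2.82-fold, while NOP10, NIP7 and FAP7, the last named after its values were seen, were 3.11-fold, 2.97-fold and 2.52-fold lower. The list's median log2 ratio was -0.09, 0.65 and 0.83 in replicates 1, 2 and 3, and it did not pass camera without both libraries of replicate 2. With the length trend removed the list no longer passed (adjusted p = 0.249), MDN1 turned to -0.52, and SDA1, NOP10 and NIP7 stood at 0.91, -0.75 and -0.98. Of 24 cell cycle genes 2 rose (0 adjusted over the list alone), MBP1 by 2.99-fold and SWI6 by 1.92-fold, which encode the 2 parts of the transcription factor MBF; this list did not pass camera without Minus_Rps26 replicate 1 or without Plus_Rps26 replicate 2. MBP1 stood at 2.23 without Plus_Rps26 replicate 1, and MBP1 and SWI6 at 0.88 and 0.25 with the length trend removed. Of 21 genes of the Rim101 pathway, which responds to alkaline pH, 1 rose, the sensor gene DFG16 (2.21-fold), as when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0817). RIM101 itself was at 0.31 ± 0.27 and NRG1 at 0.13 ± 0.34 (SE).

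**Figure D2:**
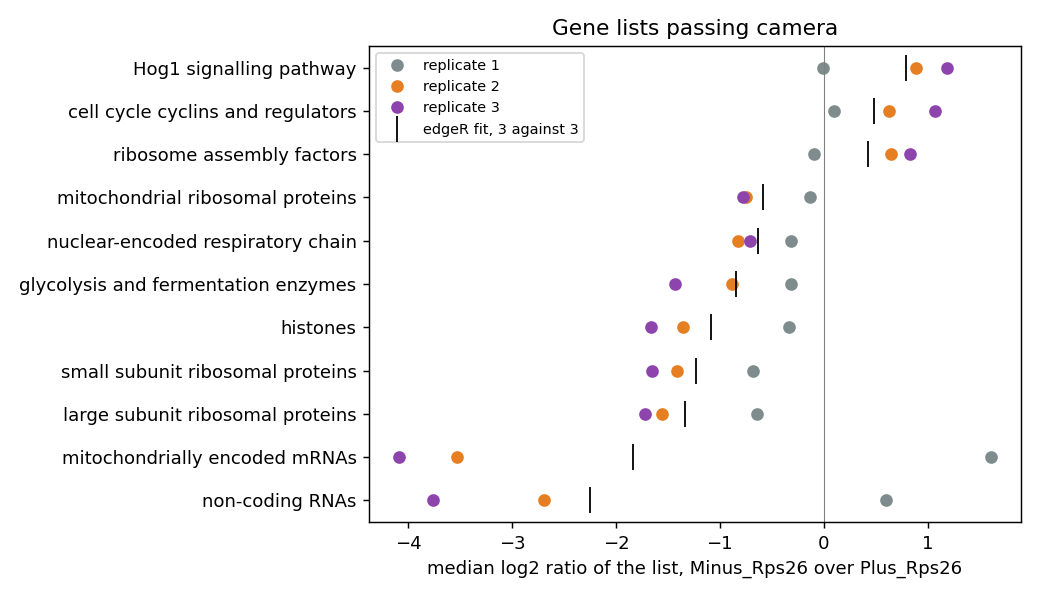
Median log2 ratio (x axis) of the members of each of the 11 gene lists that passed camera, for each replicate number (points) and from the edgeR fit (vertical lines). Ribosomal protein lists were below 0 in all 3 replicates. Respiratory chain and mitochondrial ribosomal protein medians turned positive with total-count scaling, where the median of all genes was 0.75. Non-coding RNAs and mitochondrially encoded mRNAs were at 0.60 and 1.61 in replicate 1 and below -2 in the others.

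Of the 16 lists that did not pass, several had called members. Some passed camera (preset correlation) toward lower values in Minus_Rps26 once the coding length trend was removed. These were translation factors (adjusted p = 0.0206), ergosterol synthesis (0.0181), amino acid biosynthesis (0.0005) and sulfur assimilation (0.0005). Glucose-repressed genes (0.00479) and plasma membrane transporters (0.0314) were the others, the latter at a median of -0.47 against 0.02 before. Among 37 translation factors 2 rose and 3 fell (4 and 5 adjusted over the list alone), with the eIF4G gene TIF4632 2.86-fold and the eIF5B gene FUN12 2.18-fold higher, and the eIF4E gene CDC33 2.68-fold, the eIF5A gene HYP2 2.49-fold and SUI1, the eIF1 gene, 2.26-fold lower. In the unfolded protein response list of 16 genes, the sensor gene IRE1 rose 2.08-fold, and its target HAC1 was 3.87-fold and FPR2 2.77-fold lower, as when adjusted over the list alone. Of 22 ergosterol genes HMG1 rose 2.02-fold, and ERG26 (3.25-fold), ERG2 (2.88-fold) and ERG10 (2.30-fold) fell, counts that also held adjusted over the list alone. ATG11 rose 2.84-fold and ATG5 was 3.77-fold lower among 21 autophagy genes, both also adjusted over the list alone. RPN2 rose 1.96-fold and PRE3 was 2.61-fold lower among 32 proteasome genes, and HOM6 (2.43-fold) and HOM2 (2.10-fold) were lower among 44 amino acid biosynthesis genes, none of them adjusted over the list alone. TRK1 (2.66-fold), SNQ2 (2.57-fold) and YOR1 (2.40-fold) rose among 32 plasma membrane transporters, also adjusted over the list alone. SUI1, ERG10 and YOR1 were named after their values were seen. With the coding length trend removed most of these rises nearly vanished or shrank: HMG1 stood at 0.01, IRE1 and SNQ2 at 0.06, RPN2 at 0.11, FUN12 at 0.19, TRK1 at 0.29, ATG11 at 0.46 and TIF4632 at 0.74. Among the falls FPR2 stood at -0.79 and HYP2 at -0.68 with it, and HAC1 went from -1.95 to -1.18 without Plus_Rps26 replicate 3.

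Galactose genes (9 tested), cytosolic chaperones (22) and cell wall proteins (29) had 0 calls, over all genes and adjusted over the list alone. PGM2 and GCY1 were at -0.56 ± 0.37 and -0.38 ± 0.32, SSB1 and SSE1 at -0.32 ± 0.31 and 0.17 ± 0.33, and CCW12 and CWP2 at -1.22 ± 0.42 and -0.66 ± 0.29 (log2 fold change ± SE). Each of 4 further lists had 1 call, a gene named after its values were seen. TRX2 fell among 25 environmental stress genes (1 fall adjusted over the list alone), MET8 among 18 sulfur assimilation genes (5 falls adjusted over the list alone) and ADH2 among 19 glucose-repressed genes, and STE6 rose among 20 mating genes (0 adjusted over the list alone in both). Their log2 fold changes were -1.31, -1.50, -1.79 and 1.21. The most abundant members of these lists stood at -1.64 ± 0.97 for HSP12, 0.52 ± 0.37 for HSP104, -0.52 ± 0.28 for CYS4, -0.09 ± 0.32 for CYS3, -0.56 ± 0.25 for SUC2, -0.86 ± 0.37 for ALD4, 0.57 ± 0.40 for STE2 and -0.40 ± 0.40 for MFA2 (SE). With the coding length trend removed signs changed for genes such as HSP104, SSE1, CWP2 and MFA2, to -0.29, -0.36, 0.13 and 0.50, and CCW12 and HSP12 stood at -0.48 and -0.71. With total-count scaling PGM2, GCY1, SSB1, CWP2, CYS4, CYS3, SUC2, ALD4 and MFA2 turned positive, though each stayed below the median of all genes there, 0.75. Signs differed between median and mean for environmental stress genes (0.29 and -0.01) and chaperones (-0.08 and 0.06), and cell wall proteins had positive values of both (0.13 and 0.01) with camera pointing down.

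Fold changes rose with coding length. Across 5534 nuclear protein-coding genes, which are not independent replicates, Spearman's rho of coding length with the log2 fold change was 0.688 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). In 10 groups of genes by length, the shortest, of 78 to 468 bases, had a median log2 fold change of -0.70 with 136 genes lower and 0 higher, and the longest, of 2835 to 14733 bases, a median of 1.10 with 300 higher and 0 lower. The rank correlation was 0.599, 0.647 and 0.589 within replicates 1, 2 and 3. With the length trend of each library removed, edgeR called 0 genes (1036 at an unadjusted p under 0.05).

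**Figure D3:**
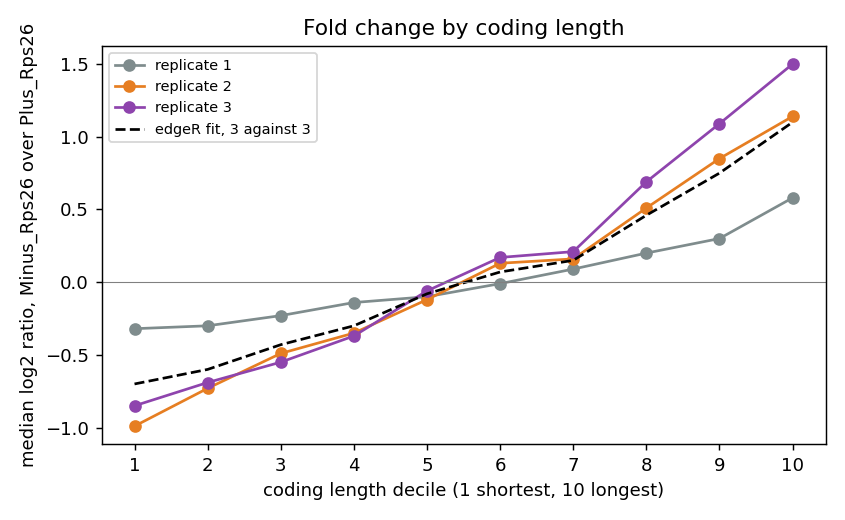
Median log2 ratio of Minus_Rps26 over Plus_Rps26 (y axis) in 10 groups of nuclear protein-coding genes by coding length (x axis), for each replicate number (solid lines) and from the edgeR fit (dashed line). The fitted median went from -0.70 in the shortest group to 1.10 in the longest, with a smaller range in replicate 1.

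The bases before the start codon, which the series title names as the element of interest, differed between lower and higher genes. Genes lower in Minus_Rps26 had A at -3 in 73.7% of 418 cases against 56.4% of 456 higher genes (odds ratio 2.17, Fisher's exact test, two-sided, p = 9.84e-08, Benjamini-Hochberg adjusted p = 4.72e-06 over 48 tests), with 61.2% among all 5520 tested genes. A at -1 was present in 54.8% against 39.5% (adjusted p = 0.000174), A at -2 in 49.8% against 37.1% (adjusted p = 0.00203) and A at -4 in 50.0% against 39.0% (adjusted p = 0.00717). In all, 16 of 48 pairs of position and base passed, 8 of them A, each more frequent in lower genes, and the other 8 were C, G or T, each less frequent there. Without cytosolic ribosomal protein genes 3 pairs passed, A at -3 (70.9% of 326 against 56.4%; adjusted p = 0.0018), A at -1 (52.1% against 39.5%; adjusted p = 0.0112) and G at -12 (9.5% against 17.5%; adjusted p = 0.0277). Lower genes set against all other tested genes gave 13 passing pairs and higher genes 0, and without Minus_Rps26 replicate 1, which left 24 lower genes, 0 pairs passed. Genes are not independent replicates, and copies of ribosomal protein genes share sequence. Lower genes were also shorter (median 610.5 against 3238.5 bases) and more abundant (median 142 against 70.4 CPM) than higher genes. No base test was matched or adjusted for length or abundance, so these differences in bases cannot be told apart from either.

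The number of matches to the yeast consensus at -6 to -1, from 0 to 6, fell with the fold change: Spearman's rho was -0.110 across 5520 genes (permutation p = 1e-05, two-sided). Median log2 fold changes were 0.18 for the 56 genes with 0 matches and -0.26 for the 161 genes with 6 matches, and the quartiles of the latter, -0.88 and 0.32, spanned more than this difference. Given mean log CPM and coding length, the partial rank correlation was -0.045 (permutation p = 0.00075), and with the coding length trend removed from the fold changes rho was -0.078 (permutation p = 1e-05, 5509 genes). Within replicates 1, 2 and 3 the rank correlation was -0.104, -0.093 and -0.105, and the partial one -0.003, -0.047 and -0.043.

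**Figure D4:**
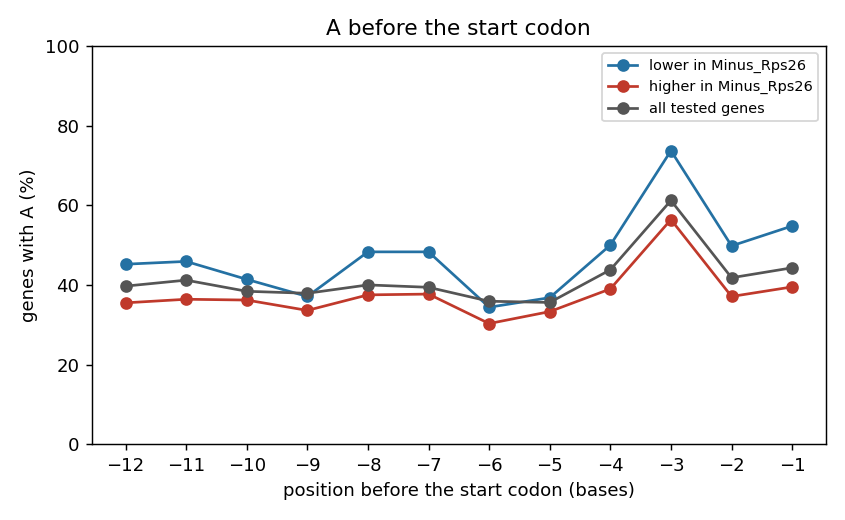
Share of genes with A (y axis, percent) at each position before the start codon (x axis) among genes lower in Minus_Rps26 (418), genes higher (456) and all tested genes (5520). The largest difference is at -3, where lower genes have 73.7% and higher genes 56.4%.

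Set against the Rps3_TAP library, Minus_Rps26 had called genes in lists such as glycolysis, histones, cytosolic and mitochondrial ribosomal proteins, the respiratory chain and assembly factors; no test of whole lists was run here. Of 5815 features 1524 passed (edgeR adjusted p under 0.05), 616 higher and 908 lower in Minus_Rps26; with total-count scaling, where the median of all genes was 1.39, 1644 were higher and 147 lower. Among called genes of the kind described above, AAD3, an aryl-alcohol dehydrogenase gene, rose by a log2 fold change of 4.72 ± 0.84 (SE). It was followed by NCA3 (15.8-fold), RED1, a meiotic chromosome gene (14.6-fold), YOR302W (14.1-fold) and NFT1 (13.9-fold). These rises are ratios over low values, 0.605 to 2.924 CPM, in the single Rps3_TAP library. The largest falls among called genes of that kind were TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene (33.1-fold lower), and DAD1, of the kinetochore (27.1-fold). PHM6 (25.5-fold), MRPL39 (22.8-fold) and CAR2, of arginine degradation (22.3-fold), came next. Outside them RPS26A fell 291-fold and the small nucleolar RNA snR84 34.2-fold, and RPS26B in Rps3_TAP was 2210 times its mean CPM in Minus_Rps26. Without Minus_Rps26 replicate 1 TDH1 and PHM6 stood at -5.71 and -5.45, against -5.05 and -4.67. All 10 histone genes and 15 of 20 glycolysis and fermentation genes fell, 40 of 54 small subunit and 57 of 81 large subunit ribosomal protein genes fell, and 28 of 77 assembly factors rose; adjusted over the list alone, 10, 18, 50 and 65 fell and 40 rose. The medians of these 5 lists kept their signs with total-count scaling. Of 68 mitochondrial ribosomal protein genes 34 fell (36 adjusted over the list alone; median -1.32, and -0.10 with total-count scaling), and of 37 respiratory chain genes 15 fell (17 adjusted over the list alone; median -1.15, which turned to 0.07 with total-count scaling). RPL7B, a large subunit gene, rose (log2 fold change 2.65) and NOP10, an assembly factor, fell (-1.75); RPL7B was named after its values were seen in this comparison. Strain and growth differ together here, Rps3_TAP is 1 library assumed to vary like the others, and edgeR called 615 without Minus_Rps26 replicate 3, 870 without Minus_Rps26 replicate 2, 2405 without Plus_Rps26 replicate 1 and 2359 with these 2 groups alone in the fit.

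Plus_Rps26 differed from Rps3_TAP in 86 of 5815 features (edgeR adjusted p under 0.05), 12 higher and 74 lower. Strain, growth and purification (gradient fraction against beads) differ together between these groups, and Rps3_TAP is 1 library. Again among genes of that kind, the phosphate transporter gene PHO89 was 13.9-fold higher, NCA3 12.6-fold, RPL7B 10.4-fold, YHR033W 9.22-fold and the zinc transporter gene ZRT1 9.17-fold. In Rps3_TAP PHO89, NCA3 and YHR033W stood at only 6.05, 2.92 and 2.72 CPM, and RPL7B and ZRT1 at 41.8 and 28.4 CPM. CAR2 was 16.0-fold lower, the malate dehydrogenase gene MDH2 15.0-fold, the riboflavin synthesis gene RIB4 13.0-fold, ICS2 12.3-fold and PHM6 11.7-fold. Of 25 environmental stress genes 5 fell (13 fell and 1 rose adjusted over the list alone), SOD2, SDP1, YGP1, DDR48 and PNC1. Of 22 cytosolic chaperones 3 fell (7 adjusted over the list alone), SSA1, SSA2 and CPR1, and of 20 glycolysis and fermentation genes 3 fell (15 adjusted over the list alone), HXK2, GLK1 and TDH1. These members were named after their values were seen, and the medians of the 3 lists were negative with total-count scaling too. Among 54 small subunit ribosomal protein genes, a list without RPS3, RPS26A and RPS26B, edgeR called 0, also adjusted over the list alone. Their median log2 fold change was -0.38. On simulated counts this comparison recovered 3% of 2-fold and 43% of 4-fold changes, so 0 calls do not show that the list is unchanged. DESeq2 called 426 genes, edgeR on nuclear protein-coding genes 141, and edgeR with total-count scaling 6, which were RPS26A, RPS26B, CAR2 and MDH2, all lower, and URA3 and RPL7B, higher. With these 2 groups alone in the fit RPS26A, CAR2, MDH2 and WSC4 passed. Leaving out 1 library gave 32 (Minus_Rps26 replicate 1), 48 (Minus_Rps26 replicate 2), 36 (Minus_Rps26 replicate 3), 29 (Plus_Rps26 replicate 3) and 586 (Plus_Rps26 replicate 1).

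Both bead-purified groups were also set against Plus_Rps26. Across 5815 features the covariance of the Minus_Rps26 over Plus_Rps26 with the Rps3_TAP over Plus_Rps26 log2 ratio was -0.121. Counts of all 7 libraries drawn around the Plus_Rps26 means, without group differences, gave 0.0908, a difference of -0.212. The 3 control libraries were drawn as well. Trends across genes that set the real control libraries apart are therefore not in the draws. The correlation was -0.149 against 0.361 simulated. Without Plus_Rps26 replicate 1 the covariance was 0.163 against 0.0952 simulated, so the sign of the difference rests on that library. The 3 control libraries cannot be divided into separate sets of at least 2, so no estimate free of shared controls was made.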

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

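The items here lie in columns and lines that the comparisons did not use, and were looked at after the data had been seen. In the authors' normalized counts for Minus_Rps26 against Rps3_TAP, the columns named for the eluates of replicates 1 and 3 held equal values in all 5734 rows above 0. Both equal the counts of Minus_Rps26 replicate 1 divided by 1.054, with no spread between the 5th and 95th percentile over 5366 genes, while the counts of replicate 3 over the column named for it ranged from 1.072 to 3.771 between the same percentiles. Entering replicate 1 in place of replicate 3 in the present fit gave 1461 called genes, against 1524 with replicate 3 and 615 with replicate 3 left out. A repeated library adds no spread of its own, so these counts do not show that the repeat matters little. That fit shares its spread with the Plus_Rps26 libraries, which the authors' columns for this comparison do not include. The effect of the repeat on the authors' calls was therefore not tested.

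Alignments that were not unique, which the count files list apart from the features, came to 11530659 in Minus_Rps26 replicate 1, 18980582 in Minus_Rps26 replicate 2, 11762367 in Plus_Rps26 replicate 1, 14508947 in Plus_Rps26 replicate 2 and 14150109 in Rps3_TAP. Replicate 3 of both groups listed 0, a difference in how such reads were handled or listed; which of the 2 was not tested. Without both libraries of replicate 3, edgeR called 0 genes between Minus_Rps26 and Plus_Rps26 (659 at an unadjusted p under 0.05).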

How the results depend on the processing

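Settings that left out whole replicate pairs, removed the coding length trend or repeated replicate 1 were chosen after the data had been seen, and except where stated the cause of a change was not tested. The 907 genes called between Minus_Rps26 and Plus_Rps26 became 1552 with DESeq2, 0 with the replicate block, 0 with the coding length trend removed (1036 at an unadjusted p under 0.05) and 0 with the replicate block and the trend removed (1058). Leaving out 1 library gave 0 to 2495 calls, and leaving out replicate pair 1, 2 or 3 gave 2671, 0 and 0. All 907 were among the DESeq2 calls and kept their sign with the replicate block and without each pair. With the coding length trend removed, 789 of the 876 of them that were tested kept their sign, and 787 with the block as well. These fits reuse libraries that picked the 907 genes, so the kept signs are not independent support. Total-count scaling called 1079, with 1042 higher and 37 lower, and moved the median of all genes to 0.75. Other settings gave 822 to 1136.

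For Minus_Rps26 against Rps3_TAP the 1524 calls became 2359 with these 2 groups alone and 615 to 2405 when 1 library was left out. For Plus_Rps26 against Rps3_TAP the 86 calls became 426 with DESeq2, 141 with nuclear protein-coding genes, 6 with total-count scaling, 4 with the 2 groups alone and 29 to 586 when 1 library was left out. The 11 lists that passed camera became 0 with an estimated correlation (adjusted p of 0.713 or more) and 0 with fry's directional test, and 10 to 15 in all other settings. The replicate block ended the call of mitochondrially encoded mRNAs. The 12 lists passing with the length trend removed held 6 of the 9 of these 11 that could be tested, without ribosome assembly factors, mitochondrial ribosomal proteins and the respiratory chain; with the block as well 4 of 9 remained, Hog1 signalling and histones being lost too.

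The 16 pairs of position and base became 3 without ribosomal protein genes, 0 for higher and 13 for lower genes against all others, 18 with a fold of 2 or more, and 0 to 18 when 1 library was left out (19 without both of replicate 1), where 24 lower genes remained without Minus_Rps26 replicate 1. Sets of lower and higher genes were empty, and no value could be had, with the replicate block, with the length trend removed, and without replicate 2 or 3 of either group or as a pair. On the fitted fold changes the match score kept its sign and its side of 0.05 in all settings run. It ran from -0.146 at 50 CPM or more to -0.045 given length and abundance. Coding length kept both as well, from 0.602 to 0.797. Within replicate 1 alone the match score given length and abundance stood at -0.003. The covariance excess of -0.212 became -0.249 with total-count scaling, -0.199 without ribosomal protein genes, and -0.324 to 0.068 when 1 library was left out, the last without Plus_Rps26 replicate 1.

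With the length trend removed, MDN1 turned to -0.52 (-0.53 with the block as well), SSK22 to -0.04 (-0.05) and SSK2 to -0.08 (-0.06), and MSB2 to -0.00 with both. Every called named gene tested there lost its call, since 0 genes were called. The replicate block, fitted to the same libraries, ended the calls of 61 of 82 named genes and reversed none. Depth was 9605899 counts or more in every library. In simulated counts of these depths and spreads 92.3% of 4-fold but 21% of 2-fold changes between Minus_Rps26 and Plus_Rps26 were recovered. A 2-fold change that did not pass is therefore not shown to be absent. The simulated genes varied independently, without trends with coding length between libraries, so recovery in the real libraries may be lower.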

Other observations

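The test of each explanation below was fixed before its own value was seen, but after library correlations and the genes of largest change had been looked at, and the patterns were found in the same data. Plus_Rps26 replicate 1 stood apart from its group: its rank correlations across genes were 0.964 and 0.933 with Minus_Rps26 replicates 1 and 2, above 0.899 and 0.874 with Plus_Rps26 replicates 2 and 3, and 0.887 with Minus_Rps26 replicate 3. Minus_Rps26 replicate 1 had 0.953 and 0.942 with its own group. Signal recognition particle RNA SCR1 was the most abundant feature in Minus_Rps26 replicate 1 (1.82% of counts) and Plus_Rps26 replicates 1 and 2 (3.24% and 4.75%), LSR1 in Plus_Rps26 replicate 3 (7.92%) and PDC1, which encodes pyruvate decarboxylase, in Minus_Rps26 replicates 2 and 3 (1.08% and 1.21%). These genes were singled out after their values were seen.

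Fold changes of Minus_Rps26 over Plus_Rps26 rose with coding length. A candidate explanation is that bead eluates as such hold longer messages than gradient fractions. Against it, the ratio of the bead-purified Rps3_TAP library over each Plus_Rps26 library fell with coding length, with rank correlations of -0.298 to -0.094. Strain and growth differ as well, and Rps3_TAP is 1 library. In the depletion strain only ribosomes made after the shift carry the tag, whereas Rps3_TAP has the tag on RPS3. A length bias of beads that take up only part of the ribosomes was therefore not tested by Rps3_TAP. Length trends between libraries of 1 class remain open: the mean size of their 6 rank correlations was 0.313 (0.154 to 0.586), just under the bound set for counting them as the cause and above the bound set against it. The presence of Rps26 and the tagging and age of the ribosomes differ together in this design, and a biological explanation was not tested.

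Ribosomal protein genes were lower in Minus_Rps26. Short length alone does not account for this: their median of -1.31 lay 0.96 below the mean of 10000 sets of other genes matched on coding length (a difference of -0.96), and below all of these sets. Matched on abundance as well, the sets had a mean of -0.85 and the difference was -0.46, again below all 10000 sets but short of the bound of 0.5 fixed for excluding the explanation. The matched genes had a median of 1060 CPM against 1670 CPM for ribosomal protein genes, so abundance was not fully matched and this explanation cannot be told apart from a property of the group. Spans with introns overstate the coding length of some ribosomal protein genes.

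The match score to the start codon consensus was lower for genes higher in Minus_Rps26. Coding length and abundance together may account for part of this, since given both the partial rank correlation was -0.045 against -0.110 without them, but with the coding length trend alone removed from the fold changes it was -0.078 (p = 1e-05); what is left given both passed its permutation test (p = 0.00075) but is under the size of 0.05 fixed beforehand. A role of Rps26 in reading these bases was not tested separately from the other differences between the classes.

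For the count of 907 called genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many, and the highest of the others gave 3. A share under 0.05 cannot be had from 10 splits. Among the 4 splits that part all 3 replicate pairs, the others gave at most 3 calls.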
